A study of Mus musculus with 4 samples.

How the data were processed

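RNA of single ESLAM SK HSCs from mouse bone marrow was measured in 4 libraries, numbered 1 to 4 in the labels. Per the labels' protocols, single cells were sorted into 8-strip tubes with settings that avoid doublets, and each cell received a barcode with the oligo-dT primer. The barcoded cDNA went through 20 cycles of PCR, was pooled, went through 4 further cycles, was sheared, enriched for 3′ ends and sequenced in paired reads of 150 bases. The deposited values are raw counts per gene and cell, whole numbers with no normalization. Per the labels, the authors used Trimmomatic 0.36, HISAT2 2.1.0, HTSeq 0.9.1 and the GRCm38 build. Whether reads were collapsed by molecular identifier is not stated, so counts may include PCR copies, and all intervals and limits cover counting error only. The median nonzero value was 18 and 14.3% of nonzero values were 1, so a count should not be read as 1 molecule. The labels do not say whether the libraries came from separate mice. Tests over libraries therefore rest on the spread between these 4 libraries, which may be technical. In the Cd27 list test the spread of each list was also drawn toward that of the other lists. In the Cd27 gene test all 4538 genes received the same standard error, 0.0618, so it did not measure the spread of a single gene.

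Each cell was placed in its library from its name. No source gives the sort gate of a cell, and no cell was assigned to a gate. The comparisons planned between CD27-positive and CD27-negative cells were therefore not run, and all libraries form 1 group of 4. Gene lists, markers, cell filters and the rule for named genes were fixed before the data were examined, and the tests of Cd27 against lists and genes were not.

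Cells were kept with at least 1000 genes detected, at least 10000 counts and at most 20% mitochondrially encoded counts. This kept 292 of 297 cells, with totals from 10653 to 346876 counts. No doublet caller was run. CPM was computed from the counts of the kept cells summed per library and scaled to the same total. Values are means with SD over the 4 libraries. Shares of cells carry 95% exact (Clopper-Pearson) binomial intervals, and for a share of 0 a limit of 3 divided by the number of cells. Gene positions came from GENCODE M21 on GRCm38.

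For phase shares, genes detected and rank correlations, each cell was thinned at random to 30000 counts with a fixed seed, and 16 kept cells below that depth were left out. Cells were scaled to 10000 counts and log-transformed. Scores of all lists, S and G2/M included, used score_genes of scanpy 1.11.5 with a control size of 50, in place of the phase function named beforehand. Clusters used 2000 variable genes, library centring, 20 principal components, 15 neighbours and Leiden clustering at resolution 0.5. A cluster was named where at least 1 marker of a type, fixed beforehand, was among its 10 leading genes and at least 3 were 2-fold above the other cells and found in 20% of its cells. Otherwise it was left unnamed. The runs of 8 cells were found by inspecting the data, and their levels are means of the CPM of single cells.

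Spearman rho of Cd27 with each of 26 list scores was computed across the cells of each library. The lists cover sorting antigens, HSC identity, quiescence and dormancy, megakaryocyte and platelet, lymphoid and multipotent progenitor, myeloid, erythroid, S phase, G2/M phase, cyclins and CDKs, immediate early and dissociation, interferon response, antigen presentation, CD27 and NF-kB signalling, oxidative phosphorylation, glycolysis, adhesion and niche, and transforming growth factor beta and BMP. They also cover markers of B cells, T and NK cells, endothelium, stroma, macrophages and mast cells, ribosomal proteins and mitochondrially encoded genes. Cd27 was left out of any score it was compared with. The test of these rho values was added after the data were seen: limma 3.58.1 tested the mean Fisher z over 4 libraries against 0, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. An exact sign flip over 4 libraries cannot give a p below 0.125, so none was used. The same limma test was run on 4538 genes detected in at least 20% of cells, with camera (preset and estimated correlation) and fry for lists. Tested on simulated data with 50 genes tied to Cd27 at each strength, the gene test recovered 22%, 74%, 100% and 100% at log2 changes of 0.5, 1, 2 and 3 per SD of Cd27, and called 8 of 4338 untied genes. The simulated genes were drawn independently given Cd27, with the same tie in every library. These rates may therefore be optimistic for the real data.

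The rule for named genes takes the sorting antigens, genes past a threshold between gates, the 4 highest members of each list and, with no gate, the 24 named genes ranked first by the number of libraries in which they were variable and then by normalized dispersion. Genes correlated with Cd27, leading genes of clusters and genes of the runs of 8 cells fall outside it and were chosen after their values were seen. Alternatives covered the cell filter, depth of thinning, detection limits, score limits, clustering settings, covariates, the runs of 8 cells and leaving out each library. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3.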

Results

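Haematopoietic stem cells (HSCs) of wild-type mice, aged 8 weeks, were sorted from bone marrow and profiled 1 cell at a time to ask how CD27-negative and CD27-positive HSCs differ. CD27 is a receptor of the tumour necrosis factor receptor family that is widely used as a surface marker of lymphoid cells and progenitors. The cells carried the ESLAM SK phenotype, that is lineage marker-negative, Kit- and Sca-1-positive, CD150-positive, CD48-negative and EPCR-positive. Each was sorted into its own tube and given a barcode during reverse transcription. Barcoded cDNA was then pooled into 4 libraries. The labels of all 4 libraries name both CD27 gates, and the cell names give the library but not the gate. The libraries therefore form 1 group (n = 4), and no comparison between CD27-negative and CD27-positive cells was made. Cells were never assigned to a gate from their Cd27 transcript. The values below describe the libraries and the relation of Cd27 transcript to other transcripts across cells.

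The count table held 13742 genes and 297 cells, with 75, 75, 74 and 73 cells in libraries 1 to 4. After filtering, 74, 75, 71 and 72 cells remained, 292 in all. Total counts of the libraries were 7417147, 8090683, 5265858 and 11215457. The median count per kept cell was 93024, 99569, 65416 and 142675, and the median number of genes detected per cell was 3070.5, 2827, 2888 and 3191. Mitochondrially encoded transcripts made up 1.42% ± 0.080 of the counts of a median cell and ribosomal protein transcripts 18.7% ± 0.60 (SD, n = 4 libraries). Over the genes above 100 CPM (library counts scaled to the same total), the median coefficient of variation between libraries was 13.0%.

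Transcripts of Ly6a, Procr and Kit, whose products were selected for in the sort, were abundant in all 4 libraries. That of Slamf1, also selected for, was less so, and that of Cd48, selected against, was rare. Ly6a, which encodes Sca-1, stood at 680 ± 93 CPM (SD, n = 4) and had a count in 92.8% ± 3.5 of cells. Procr, which encodes EPCR, stood at 296 ± 48 CPM and in 76.0% ± 2.4 of cells. Kit stood at 222 ± 17 CPM and in 85.0% ± 2.7 of cells. Slamf1, which encodes CD150, was lower, at 58.5 ± 27.5 CPM and in 25.6% ± 7.3 of cells. Cd48 had a count in 2 of 292 cells, with no cell in libraries 3 and 4. By the limit of 3 divided by the number of cells, 0 there allows up to 4.23% and 4.17% of cells with a count. The exact 95% intervals reach 5.06% and 4.99%. This limits cells with a count, not cells that express the gene. The 2 cells held 7 and 30 counts. Flt3 and Cd34, which mark multipotent progenitors, had a count in 10.3% ± 0.91 and 48.3% ± 3.3 of cells.

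Cd27 transcript had at least 1 count in over 50% of the cells of each library. The gene lies on chromosome 6 of GRCm38, at 125232622 to 125237010 on the minus strand (ENSMUSG00000030336.14, protein coding, GENCODE M21). It had a count in 40 of 74, 50 of 75, 41 of 71 and 43 of 72 cells. These shares are 54.1% (95% exact binomial confidence interval 42.1 to 65.7), 66.7% (54.8 to 77.1), 57.7% (45.4 to 69.4) and 59.7% (47.5 to 71.1). Levels were 175, 207, 223 and 150 CPM, with a mean of 189 ± 33 (SD, n = 4). With at least 3 counts asked for, the shares were 45.9%, 53.3%, 56.3% and 47.2%, a mean of 50.7% ± 4.9. How many cells of each gate entered a library is not given in the sources used here. Intervals cover counting error only.

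**Figure D1:**
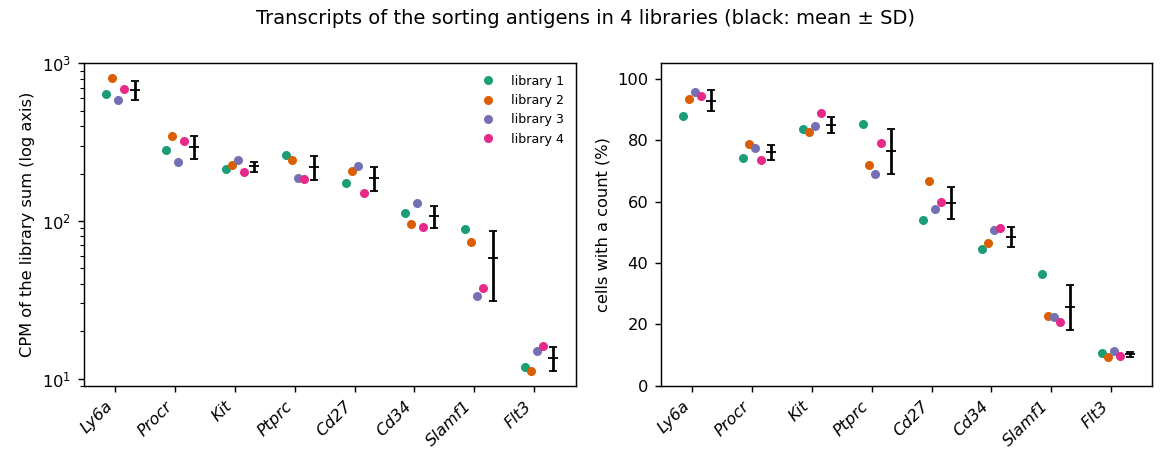
Transcript level in CPM (left, log axis) and percent of kept cells with a count (right) of 8 genes of the sorting antigens list, 1 coloured point per library, with the mean and SD of the 4 libraries in black. The list also holds Flt3 and Cd34, which are not in the sorted phenotype, and Cd48 is not drawn. Of the 8 genes Ly6a stood highest and Flt3 lowest, and Cd27 stood between 150 and 223 CPM.

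Among the lists fixed for cell types, HSC identity had the highest summed level, though the lists differ in size and the sums were not tested. All 30 members of the HSC identity list had counts, and their levels summed to 11817 ± 777 CPM (SD, n = 4). The 4 highest were Ifitm1 at 3159 ± 244 CPM, Ifitm3 at 1857 ± 156, Pdzk1ip1 at 816 ± 120 and Mllt3 at 702 ± 94. In the quiescence and dormancy list, Apoe stood at 1600 ± 55 CPM, Txnip at 1432 ± 182, Ltb at 695 ± 66 and Egr1 at 461 ± 30. The megakaryocyte and platelet list summed to 2265 ± 49 CPM, with Gng11 at 636 ± 40, Cd9 at 382 ± 12 and Fli1 at 136 ± 12. The lymphoid and multipotent progenitor list summed to 1236 ± 147 CPM, led by H2-DMa at 261 ± 26, Bcl11a at 192 ± 39, Cd27 at 189 ± 33 and Emb at 168 ± 31. Of the myeloid genes, Lyz2 (lysozyme) reached 906 ± 64 CPM, Prtn3 491 ± 41, Spi1 182 ± 24 and S100a8 89.5 ± 33.1. The erythroid list, at 3381 ± 640 CPM, was carried by Car2 (carbonic anhydrase) at 2692 ± 277, and the myeloid list summed to 1857 ± 81.

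Immediate early genes, which respond within minutes to stimulation and to tissue dissociation, were among the most abundant. Their list summed to 18272 ± 1938 CPM, with Fos at 4544 ± 720, Jun at 4337 ± 379, Dusp1 at 2041 ± 208 and Ier2 at 1477 ± 328. Antigen presentation genes summed to 22759 ± 1188 CPM, led by B2m at 11293 ± 596, H2-K1 at 4333 ± 352 and H2-D1 at 2976 ± 75. Oxidative phosphorylation genes summed to 17671 ± 1033 CPM and glycolysis genes to 4603 ± 217 CPM. The interferon response list stood at 2652 ± 539 CPM, adhesion and niche genes at 2606 ± 150 and transforming growth factor beta and BMP genes at 740 ± 98. S phase genes summed to 1926 ± 668 CPM, G2/M phase genes to 2207 ± 554 and cyclins, CDKs and CDK inhibitors to 2381 ± 51. Of the CD27 and NF-kB signalling list, Nfkbia reached 617 ± 56 CPM and Siva1, which encodes a protein that binds the tail of CD27, reached 178 ± 19.

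Markers of other cell types that the gate could hold were mostly low, but many of them were absent from the count table. It held 1 of 8 mast cell and basophil genes, 3 of 8 macrophage genes and 5 of 12 T and NK cell genes. Of the stromal, B cell and endothelial genes it held 7 of 8, 6 of 10 and 9 of 10. The sums cover the genes present and say nothing of the absent ones. The mast cell and basophil list summed to 0.067 ± 0.13 CPM, the macrophage list to 24 ± 9.5, the stromal list to 28.3 ± 14.6, the T and NK cell list to 67.7 ± 38.6, the B cell list to 104 ± 8 and the endothelial list to 448 ± 88. Most of the B cell sum came from Cd79b at 99 ± 7.2 CPM, whereas Ms4a1 stood at 0.65 ± 1.3. Most of the T and NK cell sum came from Klrb1c at 63.9 ± 34.8 CPM. Egfl7 (223 ± 67 CPM) and Emcn (89.8 ± 19.0 CPM) led the endothelial list. Both are also expressed by HSCs.

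The 24 named genes that varied most between cells, beyond what their level explains, were not tested for shared functions. Cd74 and H2-Aa, of MHC class II antigen presentation, ranked 1 and 5 and stood at 471 ± 124 and 168 ± 63 CPM (SD, n = 4). Across cells of a library they were positively correlated in all 4 libraries, with a mean Spearman rho of 0.44. Hes1, Id1, Gem, Dnajb1, Btg2, Junb, Rgs1 and Rgs2 respond early to signals. Among them Junb stood at 768 ± 88 CPM, Dnajb1 at 379 ± 93, Hes1 at 353 ± 110, Rgs1 at 352 ± 135, Btg2 at 257 ± 37, Rgs2 at 221 ± 35, Gem at 109 ± 25 and Id1 at 75.2 ± 53.2. Interferon-inducible Iigp1, Rtp4 and Ifi27 stood at 170 ± 57, 161 ± 19 and 179 ± 32 CPM. Hbb-bt (a globin) and S100a8 (a neutrophil protein), at 89.7 ± 23.9 and 89.5 ± 33.1 CPM, had a count in 28.8% ± 3.8 and 24.6% ± 5.0 of cells. The other variable genes were Serpina3g (1113 ± 170 CPM), Hist1h2bc (327 ± 83), Myl10 (313 ± 115), Stxbp4 (218 ± 24), Serpina3f (82.2 ± 39.5), Ramp2 (80.3 ± 37.8), Nupr1 (77.5 ± 14.0), Cd69 (48.8 ± 37.4) and Wfdc17 (37.0 ± 3.4).

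Proliferation genes differed in how many cells held them. Mki67 had a count in 17 of 292 cells, and 97.1% of its counts came from 10 cells. For Birc5 and Ccnb2 the 10 highest cells held 97.6% and 99.3% of the counts. Top2a, Cdk1 and Pcna were spread more widely, in 52, 59 and 172 cells, and their 10 highest cells held 65.9%, 53.7% and 32.8% of the counts. Ccnd2, a cyclin of early G1, had a count in 279 of 292 cells at 974 ± 99 CPM, and Cdk6 in 54. The CDK inhibitor genes Cdkn1c and Cdkn1b had counts in 67 and 37 cells. After thinning each cell to 30000 counts, 31.9%, 35.7%, 46.9% and 38.6% of cells in libraries 1 to 4 had an S or G2/M score above 0, a mean of 38.3% ± 6.3 (SD, n = 4). The exact 95% binomial intervals ran from 21.4 to 44.0 in library 1 and from 34.3 to 59.8 in library 3. With a score above 0.1 asked for, the shares were 5.56%, 4.29%, 15.6% and 4.29%, a mean of 7.44% ± 5.5, and of 4.71% ± 0.73 without library 3. A score above 0 is relative to control genes, so these shares are not shares of dividing cells. Cells under 30000 counts were left out, 2, 5, 7 and 2 per library. Without thinning the mean share was 37.4% ± 7.1. Thinned cells had a median of 2613 ± 91 genes detected per library (SD, n = 4), against 2994 ± 167 with counts as deposited.

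Clustering of the 292 cells gave 6 clusters, of which only 1 met the marker rule for a name. Cluster 4, with 8 cells, was cycling-like: Birc5, Ccnb2 and Rrm2 were among its 10 leading genes and all 10 cycling markers were at least 2-fold above the other cells. It held 7.04% of library 3 (95% exact interval 2.33 to 15.7) and 1.33% to 1.39% of each of the other libraries. The cluster with the highest cycling markers also had 8 cells without centring and with Cd27 left out, but 23 at resolution 1, 60 with cell cycle genes left out and 82 without the runs described at the end. Cluster 0 (114 cells) was led by Plekhf2, Ramp2, Xdh, Clu, Neo1, Gem and Myof. Cluster 1 (33 cells) was led by Atf3, Id1, Cyr61, Hes1, Dnajb1, Cdkn1a and Nr4a1. Cluster 2 (72 cells) was led by Cd69, Serpinb1a, Syk, Icam1 and Sox4. It had Flt3 counts in 17 cells, of 30 in all clusters. Cluster 3 (50 cells) had Fos at 224 ± 190 CPM (SD, n = 4 libraries), against 4862 ± 661 in cluster 0. Clusters 0, 1, 2 and 3 took 39.0% ± 2.7, 11.3% ± 6.1, 24.7% ± 1.1 and 17.1% ± 3.3 of the cells of a library. Cluster 5 (15 cells) was made up of the runs of consecutively numbered cells described at the end. Cd27 was among the genes used for clustering. With Cd27 left out, 5 clusters formed, and Cd27 had a count in 9 of the 46 cells (19.6%) of the cluster that took in all 33 cells of cluster 1, against 114 of 168 (67.9%) in the largest. The adjusted Rand index between the clusterings with and without Cd27 was 0.50.

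**Figure D2:**
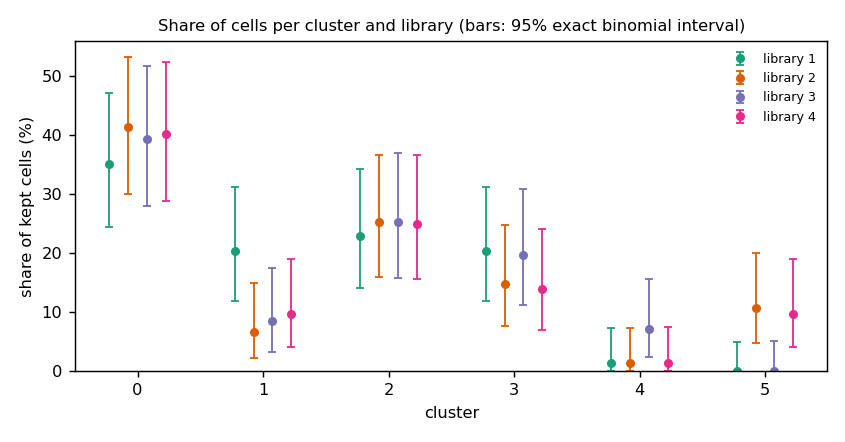
Percent of the kept cells of each library in each of the 6 clusters, 1 coloured point per library, with 95% exact binomial intervals. Cluster 4 held 7.04% of library 3, and cluster 5 had cells in libraries 2 and 4 alone.

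Across cells of the same library, cells with more Cd27 transcript had lower scores for stem cell, dormancy and platelet genes and higher scores for lymphoid and multipotent progenitor genes. Set against all other genes, these lists did not pass: camera adjusted p with an estimated correlation was 0.27 for HSC identity, 0.43 for dormancy, 0.27 for platelet genes, 0.43 for lymphoid genes and 0.43 for cyclins. The mean Spearman rho over the 4 libraries was -0.29 ± 0.15 (SD, n = 4) for the quiescence and dormancy list (limma adjusted p = 0.0118) and -0.22 ± 0.058 for HSC identity (limma adjusted p = 0.0118). It was -0.21 ± 0.082 for the megakaryocyte and platelet list (limma adjusted p = 0.0185) and -0.20 ± 0.089 for cyclins, CDKs and CDK inhibitors (limma adjusted p = 0.0211). For the lymphoid and multipotent progenitor list, scored without Cd27, it was 0.20 ± 0.12 (limma adjusted p = 0.0219). All 5 had the same sign in 4 of 4 libraries. They are not separate findings: across cells, the dormancy score had a mean rho of 0.44 with HSC identity (2 shared genes), 0.32 with platelet genes and 0.44 with immediate early genes (2 shared genes), and dormancy and cyclins share 3 genes. In library 3 the dormancy rho was -0.064, against -0.39, -0.37 and -0.35 in libraries 1, 2 and 4. The other 21 of 26 lists did not pass the threshold, with adjusted p from 0.145 to 0.855. Among these were myeloid (0.13 ± 0.10), immediate early and dissociation (-0.16 ± 0.21), G2/M phase (-0.12 ± 0.17), S phase (0.068 ± 0.16), the sorting antigens (0.041 ± 0.15) and CD27 and NF-kB signalling (-0.074 ± 0.053). Cells are not independent replicates, so the test runs over the 4 libraries. Limma also drew the standard error of each list toward that of the other lists, some of which share genes. The p-value of a list therefore does not rest on its own 4 libraries alone. Without library 2, or without library 4, 0 of 26 lists passed in limma, with 5 and 6 lists at an unadjusted p below 0.05 and a lowest adjusted p of 0.0795 and 0.0925. Across 11 alternative settings, these among them, mean rho ran from -0.371 to -0.188 for dormancy and from -0.269 to -0.124 for HSC identity. It ran from -0.242 to -0.175 for platelet genes, from -0.234 to -0.120 for cyclins and from 0.0789 to 0.253 for lymphoid genes.

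**Figure D3:**
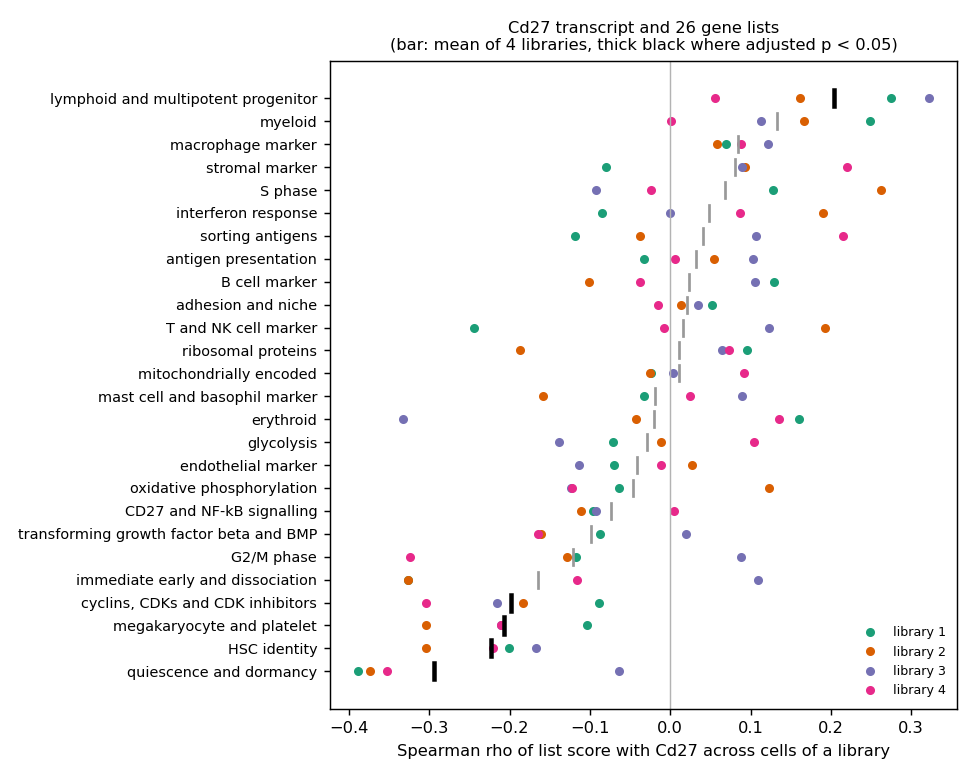
Spearman rho, across the cells of a library, of Cd27 transcript with the score of each of 26 gene lists, 1 coloured point per library, with a bar at the mean of the 4 libraries. Bars are thick and black for the 5 lists with an adjusted p under the threshold of 0.05, and their points lie on 1 side of 0.

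Single members passed in some of these lists and not in others. In the dormancy list 4 of 11 tested members were negatively and 1 positively correlated when adjusted over the list alone, against 1 negative over all genes tested. Apoe (mean rho -0.27), Socs2 (-0.20), a feedback inhibitor of cytokine signalling, Sult1a1 (-0.17) and Egr1 (-0.15) were negative, and Zfp36l2 (0.17) was positive. In the HSC identity list Ctnnal1 (-0.20), Cd81 (-0.18) and Sult1a1 (-0.17) passed when adjusted over the list alone, 3 of 24, and 0 passed over all genes, while 7 of the 24 had a positive mean rho. In the megakaryocyte and platelet list Vwf (-0.22), which encodes von Willebrand factor and marks platelet-biased HSCs, and Cavin2 (-0.21) passed when adjusted over the list alone, 2 of 11, and 0 over all genes. None of the 5 tested lymphoid and multipotent progenitor genes passed singly, though all 5 had a positive mean rho, with Cd34 at 0.14 and Emb at 0.12. None of the 8 tested cyclin and CDK genes passed singly, with Max at -0.17, Mycn at -0.12 and Ccnd2 at -0.10. Of the immediate early genes, Klf6 (-0.25), Jun (-0.20), Klf2 (-0.19), Dnajb1 (-0.18) and Egr1 (-0.15) passed when adjusted over the list alone, 5 of 16, and Klf6 passed over all genes. All 16 had a negative mean rho. As sets of genes against all others, immediate early (camera adjusted p = 1.13e-09), megakaryocyte and platelet (0.00111), HSC identity (0.00143) and dormancy genes (0.00242) passed with a preset correlation between genes. None of the 4 held with an estimated correlation, which gave adjusted p = 0.43, 0.27, 0.27 and 0.43. Lymphoid and cyclin genes did not pass with the preset correlation either (camera adjusted p = 0.0579 and 0.171). By fry, which tests whether the genes of a set move 1 way on balance, 0 of 20 lists passed, with adjusted p = 0.0593 for cyclins, 0.110 for HSC identity, 0.110 for megakaryocyte and platelet, 0.151 for lymphoid and 0.563 for dormancy genes.

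Of 4538 genes detected in at least 20% of cells, 13 were correlated with Cd27 transcript at an adjusted p below 0.05, 7 positively and 6 negatively. Among the positive genes were Rnase6 (mean rho 0.28 ± 0.10, SD, n = 4 libraries), Lyz2 (0.28 ± 0.067), Ramp1 (0.27 ± 0.14), Taldo1 (0.26 ± 0.22), Cd37 (0.24 ± 0.13) and Ctla2a (0.23 ± 0.10). Lyz2 encodes lysozyme and Cd37 a tetraspanin of leukocytes. The negative genes were Apoe (-0.27 ± 0.066), Klf6 (-0.25 ± 0.17), Nt5c3 (-0.25 ± 0.12), Xdh (-0.25 ± 0.023), Fhl1 (-0.24 ± 0.079) and Eif1 (-0.22 ± 0.23). Limma adjusted p was lowest for Rnase6, Lyz2 and Ramp1, at 0.00522 each, and highest for Ctla2a and Eif1, at 0.0466 each. The sign was the same in 4 of 4 libraries for all of the 13 but Taldo1 and Eif1, which had it in 3 of 4. Limma gave all 4538 genes the same standard error of the mean Fisher z, 0.0618, so a gene with a wide spread between libraries was not held back by it. These 13 were chosen after their values were seen. Procr, Kit and Slamf1 used in place of Cd27 gave 0 genes each in limma, with 243, 324 and 252 at an unadjusted p below 0.05 against 361 for Cd27, and Ly6a gave 3. Without library 1 the limma count was 0, with 309 genes at an unadjusted p below 0.05, and it was 3 and 5 without library 2 and without library 4. Without library 1 all 13 kept their sign and 12 kept at least 0.75 of their rho, with absolute rho from 0.124 to 0.303, though the 13 had been picked on all 4 libraries.

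In libraries 2 and 4, 8 cells with consecutive numbers each (26 to 33 and 9 to 16) stood apart from all other cells. The tubes came in strips of 8, but whether cell numbers follow the order of tubes is not known here. Of the 16 cells, 15 passed the cell filter, and the levels, ratios and shares of cells given here cover all 16. Actb averaged 321 CPM in these 16 cells against 3595 CPM in the other cells of these libraries, Rpl13 333 against 7536 and Fos 328 against 5319. B2m was at 27895 against 11327 CPM, Ly6a at 1791 against 705 and Cd27 at 439 against 185. Of 10 HSC markers, 5 had a log2 ratio below -1 and 3 a ratio above 0. Meis1, an HSC transcription factor, had a count in 62.5% of these cells and 94.7% of the others, and Ctnnal1 in 12.5% and 30.3%, whereas Mecom had a count in 93.8% and 94.7%. Across 1897 genes above 100 CPM, the log2 ratio of these cells to the others had a Spearman rho of -0.41 with the GC content of the first 300 transcript bases. Genes are not independent replicates. Without these cells 5 lists and 14 genes were correlated with Cd27, and 11 of the 13 genes above were among them.

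**Figure D4:**
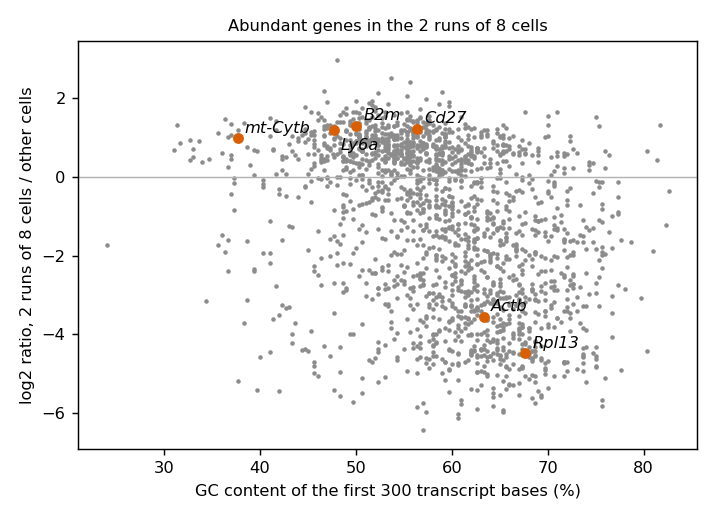
Log2 ratio of mean CPM in the 2 runs of 8 cells to that in the other cells of their libraries (pseudocount 5 CPM), against the GC content in percent of the first 300 transcript bases. Each of the 1897 grey points is a gene above 100 CPM, and Actb and Rpl13 lie far below 0 while B2m, mt-Cytb, Ly6a and Cd27 lie above it.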

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

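The tests of GC content and of low depth in the runs of 8 cells, the bootstrap interval of the HSC markers and the values without cycling-like cells were chosen after the results were seen.

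Among 212 values with 1 number per library, 26 had a single library far from the other 3 by Dixon's test. Chance puts about 1 in 20 values apart, which is 10.6 here. Library 3 was the one apart in 9, library 2 in 8, library 1 in 6 and library 4 in 3.

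Library 3 held more cycling-like cells and more of the transcripts they carry. Cluster 4, the cycling-like cluster, took 7.04% of its cells, against 1.33% to 1.39% in the others, a split that depends on the clustering setting. Its S phase list summed to 2918 CPM and Blvrb, of haem breakdown, stood at 236 CPM, while Ccnd2 was lower there, at 827 CPM. With cycling-like cells left out of every library, the S phase sum was 1412 CPM in library 3 against 1441 ± 55 in the others (SD, n = 3), Blvrb was 120 against 87.5 ± 9.0 and Ccnd2 was 918 against 1042 ± 7.2. These cells were grouped by such transcripts, so a lower S phase sum without them is built in.

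Hbb-bt stood at 126 CPM and S100a8 at 139 CPM in library 3, and were at 130 and 165 CPM there without its cycling-like cells. The immediate early and dissociation list was lower in library 3, at 15389 CPM. The rho of Cd27 with the quiescence and dormancy list was -0.064 in library 3, against -0.35 to -0.39 elsewhere. Col1a1, a collagen gene, stood at 17 CPM in library 3, from 89 counts.

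In library 2, H2-Aa stood at 262 CPM, Myc at 377 CPM and the CD27 and NF-kB signalling list at 2052 CPM. Ms4a1 at 2.60 CPM, Cd3d at 0.742 CPM and Vcam1 at 4.94 CPM rest there on 21, 6 and 40 counts, and the stromal list was lower, at 6.55 CPM. The rho of Cd27 with ribosomal protein genes was -0.19 in library 2. In library 1, Slamf1 had a count in 36.5% of cells, against 20.8% to 22.7% in the others, and cluster 2 took 23%. Cd4 at 1.75 CPM, Lum at 3.51 CPM and Cpa3 at 0.270 CPM, which alone makes the mast cell and basophil sum of 0.270 CPM, rest in library 1 on 13, 26 and 2 counts. Dixon's test says little where the other libraries have 0 or few counts, as for these genes, Ms4a1, Cd3d, Vcam1 and Ebf1. In library 4, Wfdc17 stood at 42.0 CPM, Ebf1 at 3.39 CPM (38 counts), and the rho of Cd27 with CD27 and NF-kB signalling was 0.0044.

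The 2 runs of 8 cells tended to have lower levels of GC-rich transcripts than the other cells. Across abundant genes, rho of their log2 ratio with the GC content of the first 300 bases was -0.41 for both runs together. It was -0.39 and -0.38 for the runs of libraries 2 and 4 alone, against -0.067 to 0.077 in 207 other windows of 8 consecutive numbers. Those windows overlap, so they are not 207 separate controls. A GC bias in these cells may account for part of the pattern. Actb (63.3% GC) and Rpl13 (67.7%) followed it, with log2 ratios of -3.55 and -4.49. Other genes did not: Kit (65.0%) and Mllt3 (64.3%) had log2 ratios of 1.03 and 0.91. Meis1 (47.7%) and Ctnnal1 (48.7%) had log2 ratios of -1.49 and -1.87. Low depth is argued against: other cells of the same libraries with totals in the same range had 21.4 times the median Actb level, at 3559 against 166 CPM. The median log2 ratio of 10 HSC markers was -0.93. By the rule set beforehand, a median above -1 counts against cells of another type. The bootstrap interval, added afterwards, ran from -1.87 to 0.40 and spans that bound. Cells of another type therefore cannot be told apart from the bias. No biological explanation from the design was tested, because the gate of these cells is not known.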

How the results depend on the processing

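The settings thinned to 10000 counts, given a covariate, without the 2 runs of 8 cells, with Cd27 left out of clustering and with counts of 1 and 2 set to 0, every setting of the Cd27 gene count, and leaving out libraries for Cd27 correlations and library values, were chosen after the data were seen. The comparisons of genes and lists between CD27-positive and CD27-negative cells, and the other settings meant for them, were not run because no source gives the gate of a cell. No paired analysis was possible because the libraries form a single group.

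The number of lists correlated with Cd27, 5 in the first setting, was 0 in limma with no cell filter (4 at an unadjusted p below 0.05), where thinning left 4199 counts per cell, and 0 to 6 with a library left out: 0 without library 2 and 0 without library 4. The 5 lists kept their sign in all 11 settings, which says little of their stability. Leaving out a library could not change it, since each list had the same sign in all 4 libraries. The other settings reuse most of the same cells. The lowest to highest adjusted p was 5.36e-06 to 0.0972 for dormancy, 5.62e-05 to 0.297 for HSC identity and 0.00362 to 0.685 for the lymphoid list. The number of genes correlated with Cd27, 13 at first, was 1 with no cell filter, 7 when thinned to 10000 counts, 4 given the immediate early score, 27 with counts of 1 and 2 set to 0, and 0 to 9 with a library left out. Fewer counts or fewer libraries enter most of these settings; for the immediate early score and for counts of 1 and 2 the cause was not tested.

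The phase share, 38.3%, was 7.44% with a score above 0.1 (4.71% without library 3), by the higher limit itself. Genes detected, 2613, were 2074 with at least 3 counts, 2130 when thinned to 10000 counts and 2994 as deposited, each set by the depth or limit used. Of 164 values of libraries, 164 moved by less than the spread between libraries with no cell filter and 163 did so without the runs of 8 cells. Leaving out a library cannot move a mean of 4 by that much and says nothing of their stability. Lifting the cell filter says little of it either, since kept cells held 31959650 of 31989145 counts. The number of clusters was 4 to 7 across settings, and the cluster with the highest cycling markers, 8 cells at first, had 23 at resolution 1, 60 with cell cycle genes left out and 82 without the runs; the cause was not tested.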

Other observations

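The measures at 1 or 2 counts and the values of cycling-like cells were chosen after the results were seen, as was the set of genes correlated with Cd27.

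The 8 cycling-like cells had lower levels of stem cell and immediate early transcripts than the other 284. Their median sum was 6274 against 12094 CPM for HSC identity genes, 6163 against 17170 CPM for immediate early genes, 10122 against 1256 CPM for S phase genes and 23300 against 16626 CPM for oxidative phosphorylation genes. Ly6a was at 212 against 716 CPM, Hlf at 92.6 against 393, Procr at 151 against 313 and Kit at 101 against 225. Hmgb2 was at 2236 against 300 CPM. These cells were grouped by their expression, and their number depends on the clustering setting, so no test was made, and 5 of the 8 came from library 3. Without the erythroid cell described next, which is among the 8, Ly6a was at 247, Hlf at 86.0, Procr at 190 and Kit at 96.4 CPM, and the median HSC identity sum was 6519 CPM.

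A single cell of library 3, number 22, carried erythroid transcripts at a high level. TER-119 was in the lineage cocktail of the sort, but its surface level on this cell is not known here. It had the highest total of the kept cells, 346876 counts, and 5821 genes. Its erythroid list summed to 17274 CPM, against a median of 2854 and a maximum of 14456 in the other cells. It had 1177 counts of Car1 (carbonic anhydrase), 182 of Rhd, 162 of Tfrc (the transferrin receptor), 119 of Klf1 and 78 of Gata1. It also had 41 counts of Kit, 41 of Hlf, 27 of Ly6a, 11 of Cd27, 1 of Mecom and 0 of Procr. No doublet caller was run, so a doublet cannot be told apart from a single cell here.

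The 13 genes correlated with Cd27 are a hypothesis about cell states that differ in Cd27 transcript. Chance pairing of cells is argued against, since 0 of 100 shuffles of Cd27 gave as many genes, with a highest count of 1. Genes detected per cell and the runs of 8 cells are also argued against as the whole cause, since 100% and 84.6% of the 13 kept an adjusted p below 0.05 with each removed. Given the immediate early score, 92.3% kept their sign and at least 0.75 of their rho, but 4 of the 13 stayed past the threshold, with absolute rho from 0.181 to 0.266. The relation may follow the mix of gates in a library, which was not tested.

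Genes with most of their counts in 1 cell also appeared at low counts in other cells. In cells with the same number in another library they had a count in 44 of 251 pairs (17.5%), against 4.76% for other numbers, a ratio of 3.68, which is consistent with exchange between libraries. At 1 or 2 counts the ratio was 6.00, and 5.31 without cell number 22. Car1 had 1177 counts in cell 22 of library 3 and 2, 0 and 4 in cell 22 of libraries 1, 2 and 4. Exchange within the pool of a library cannot be told apart from other sources, since its ratio was 1.18 in library 1 and 1.59 to 2.16 in the others, where a ratio above 1.5 in every library had been asked for.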
